A study of Mus musculus with 3 samples.

How the data were processed

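The samples were 3 libraries of 1 pool of cells: mRNA, hashtags and antibody tags. Cells came from the small-intestinal epithelial fraction of 8 mice, were enriched for CD45 on magnetic beads, and were sorted for lack of CD3 and for CD11b, CD11c or both. Per the labels, libraries were made with 10x 3' v3 reagents, and the submitters' processing notes name Cell Ranger 7.0.0 and mm10. The deposited matrix holds counts, as unique molecular identifiers (UMIs) per feature and cell barcode, for barcodes called as cells; no normalization had been applied. Other deposited columns hold feature names, barcodes and the tag reference, which are no measured values. The 8 hashtags were taken to mice by the labels. The labels name 14 antibodies in full, and no file pairs them with the 21 tag numbers, so tag names were taken by the order of that list. Of the 11 listed antibodies whose gene had UMIs in at least 50 myeloid cells, 7 had their own tag as the one best correlated with the transcript across cells, and only these 7 are used by name. A further 3 genes were too rare to check, and 7 tags had no listed name. The hashtag library gave 1390019 counts and the antibody tags 1166676, with a median of 239 tag counts per assigned cell.

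Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 103. Cells were assigned to mice with HTODemux in Seurat 5.3.0 under R 4.3.3 (centred log ratio, positive quantile 0.99, seed 42). Cells with more than 1 hashtag (22.4%, median 8266 UMIs) or none (2.05%, median 954 UMIs) were left out of all values per mouse. About 99.9 doublets of cells from the same mouse would be expected among the assigned cells, and hashtags cannot show them. Clustering used scanpy 1.11.5 with leidenalg 0.10.2 in Python 3.11.15: counts per 10000 on the log scale, 2000 variable genes, 30 principal components, 15 neighbours, resolution 1 and seed 0. Genes seen in fewer than 3 cells, hashtags, antibody tags and every gene of the fixed lists were kept out of the clustering. Clusters were named by hand from fixed marker lists and their top 10 genes. The cluster led by interferon-stimulated genes was named pDC-like because all 18 pDC markers were raised in it. A class entered a comparison with at least 10 cells in at least 6 mice, or in at least 3 mice of each sex. This left out the migratory dendritic cell-like cells and 3 unnamed classes, and kept 6 mice for cDC2-like and T/IEL-like cells.

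The gene lists, marker lists, comparisons, tests and rules for named genes were fixed before the data were examined. The lists were interferon lambda, type I interferon, interferon gamma, interferon receptors, nucleic acid sensing, interferon-stimulated genes, MHC class II presentation, cytokines and chemokines, endoplasmic reticulum and secretion, dissociation and immediate early response, and a check on sex labels. Mx1, Mx2, Sting1 and Trgc1 were not among the feature names; the gene of Sting1 was read under its older symbol Tmem173. The interferon lambda and type I levels are summed counts per 1000000 UMIs (CPM) per mouse and class. They were compared with the other assigned cells of the same mouse by exact two-sided sign-flip permutation tests in numpy 2.4.6 and pandas 2.3.3. Shares of cells with a UMI were compared after thinning to 1000 UMIs, as the expected share by the hypergeometric formula. Intervals are 95% exact Poisson for counts and Clopper-Pearson for shares (scipy 1.17.1). The floor behind a count of 0 is 3 counts over the class.

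Gene comparisons used counts summed per mouse and class, filterByExpr, TMM scaling and the quasi-likelihood test of edgeR 4.0.16, with Benjamini-Hochberg adjustment and a threshold of 0.05. Between classes, 22 sums entered, with the mouse as a block, and pDC-like cells were set against the equally weighted mean of macrophage-like and cDC2-like cells. Between sexes, each class had its own fit without a block. Genes given on the sex chromosomes were counted apart, and genes with no given chromosome were counted with the rest. Lists with at least 3 tested genes went to camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Antibody tags were compared as log2 of tag counts per 10000 plus 1, by exact sign-flip permutation tests per mouse, adjusted over the tags. Class shares were compared by an exact two-sided permutation test of 4 against 4 mice. The interferon genes named are those with at least 1 UMI. In each list up to 4 genes with the largest log2 fold change are named, among those called with the same direction in all mice but at most 1. Per sex and class up to 6 called genes are named, among those whose mice do not overlap, and up to 6 tags per direction.

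The tests were tried on simulated data with the spread of the real sums, in which 200 genes were changed. For the class comparison, 85% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered. For male against female mice, 2-fold changes were recovered for 90.9% of genes in pDC-like, 63.8% in macrophage-like, 65.6% in cDC2-like and 82.0% in T/IEL-like cells, and 4-fold changes for 100% in each. The 1.5-fold changes were recovered for 55.6%, 15.6%, 22.2% and 37.9%. These shares are of the changed genes that passed the low-count filter. Unchanged genes made up 13 of 179 calls between classes, and 7 of 162, 6 of 107, 3 of 107 and 7 of 137 between sexes, in the same order of classes. Apart from the changed genes the simulated sums shared 1 profile. The shares thus do not cover the real class comparison, in which 2188 of 3180 genes were called.

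Each result was recomputed with a stricter cell filter (at least 500 genes, at most 5% mitochondrial UMIs), with a hashtag rule of at least 10 counts and 70% of the cell's hashtag counts, without doublets called by Scrublet, and with clusters at resolution 0.5. Where they apply, the following were also tried: a gate of at least 4 pDC markers, mice with at least 1 pDC-like cell, other thinning depths, no mouse block, DESeq2 1.42.0 as scaling and as test, no filter on low counts, sums of at least 20 cells, an estimated correlation, a block on the mouse number, a denominator of myeloid cells, a centred log ratio of tags, and each mouse left out. Alternatives chosen after seeing the data were leaving out the single cell with most interferon lambda UMIs, the clusters in which most cells carried more than 1 hashtag, the pDC-like cluster led by interferon-stimulated genes, or the macrophage-like cluster of low UMI counts. Figures were drawn with matplotlib 3.10.9.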

Results

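Small-intestinal myeloid cells of 8 C57BL/6J WT mice, 4 male and 4 female, were measured in 1 pool by droplet sequencing of 3' mRNA. The pool was sorted from the epithelial fraction for cells without CD3 and with CD11b, CD11c or both, after enrichment for CD45. A hashtag antibody marked the mouse of each cell, and 21 antibody tags read surface proteins on the same cells. The matrix held 32285 genes and 15973950 mRNA molecules (UMIs), with a median of 4424 UMIs and 1888 genes per barcode. After filtering, 2288 of 3028 cells carried 1 hashtag and went to a mouse, 678 carried more than 1 and 62 carried none. The 8 mice had 228 to 366 assigned cells each, with 980634 to 1463863 UMIs per mouse and median depths of 3861 to 4558.5 UMIs per cell. The mouse was the replicate throughout.

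The hashtag labels were checked against sex-linked genes. Xist, the RNA that silences an X chromosome in females, was seen in 75.7% to 87.3% of the cells of each female mouse and in 1.11% to 2.25% of the cells of each male mouse. Ddx3y, on the Y chromosome, was seen in 26.3% to 35.2% of male cells and in at most 0.273% of female cells. The other Y-linked genes gave the same split. Kdm5d was seen in 5.6% to 13.8% of male cells and at most 0.656% of female cells. Eif2s3y was seen in 20.7% to 28.9% of male cells and at most 0.273% of female cells. Uty was seen in 14.8% to 16.8% of male cells and in 0% of female cells. No mouse stood on the wrong side for its label.

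The assigned cells fell into 15 clusters and 8 classes, named from fixed marker lists. Plasmacytoid dendritic cell (pDC)-like cells made up 61.3% of them, with 1403 cells and a median of 4607 UMIs. Macrophage-like cells made up 21.3%, with 487 cells and a median of 1075 UMIs. Of these, 393 came from a single cluster with a median of 945 UMIs, whose top 10 genes held 5 macrophage markers and 2 enterocyte markers. Dendritic cells of the conventional type 2 (cDC2-like) made up 6.64%, with 152 cells and a median of 6865 UMIs. Cells resembling T cells or intraepithelial lymphocytes (T/IEL-like) made up 7.34%, with 168 cells and a median of 2985.5 UMIs. There were 34 migratory dendritic cell-like cells, with a median of 3244 UMIs. The remaining small groups held 26 cycling cells, 11 cells of mixed markers and 7 cells of the B lineage.

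The series design asks which cells are the source of interferon lambda transcripts at homeostasis. Interferon lambda UMIs were found in pDC-like cells and in none of the other assigned cells. With the alternative hashtag rule, 1 of 1013 other cells held 1 UMI, against 50 UMIs in 1503 pDC-like cells; that cell was of mixed markers, had UMIs of 16 pDC markers and carried more than 1 hashtag in the assignment used here. Ifnl2 gave 43 UMIs and Ifnl3 gave 6, in 24 of 1403 pDC-like cells. The summed level per mouse was 8.38 ± 13.3 counts per 1000000 UMIs (CPM; SD, n = 8) in pDC-like cells and 0 in the other cells. It was above 0 in 7 of 8 mice (exact two-sided sign-flip permutation test, p = 0.0156). With 0 in the other cells of each mouse, this p follows from the number of mice with a UMI alone. Mouse by mouse the zeros say little, as at its own pDC-like level 20.4 UMIs would have been due in the other cells of Male4 but at most 2.46, under the floor of 3, in those of each other mouse. Over all mice the pDC-like level was 7.49 CPM, with a 95% Poisson interval of 5.54 to 9.90. This was at least 7.09-fold higher than the floor of 3 counts over all other assigned cells together. At the pDC-like level 21.3 UMIs would have been due in those cells, and 0 were seen. Counted by cells, at the pDC-like rate of positive cells per UMI, 10.4 positive cells would have been due there and 3.84 in cDC2-like cells. Against single classes the bounds were lower, at least 2.07-fold for macrophage-like and at least 2.62-fold for cDC2-like cells. These values rest in large part on Male4, which gave 27 of the 49 UMIs. Without Male4 the level over all mice was 3.74 CPM, at least 2.92-fold higher than the floor of all other cells together, with 8.75 UMIs and 6.36 positive cells due there. For macrophage-like and cDC2-like cells alone 2.72 and 2.70 UMIs would then have been due, under the floor of 3, so no bound is left against either class; 1.96 positive cells would have been due in cDC2-like cells. Without the 1 cell of Male4 that held most UMIs the bounds were at least 4.20-fold for all other cells (12.6 UMIs due), at least 1.22-fold for macrophage-like and at least 1.55-fold for cDC2-like cells.

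The level differed widely between mice, and 1 cell of Male4 set much of the mean. Male4 stood at 40.6 CPM, while the other mice lay between 0 in Female3 and 7.29 CPM in Male3. A single Male4 cell held 20 of the 49 UMIs, 16 of Ifnl2 and 4 of Ifnl3, among 6810 UMIs in all. That cell lay in the pDC-like cluster led by interferon-stimulated genes and also held the 1 Ifnb1 UMI of the assigned cells. The next cell held 5, and 21 of the 24 positive cells held 1 UMI each. Without Male4 the mean was 3.77 CPM (exact sign-flip permutation p = 0.0312), and without that cell alone it was 4.63 ± 3.57 CPM (SD, n = 8; exact sign-flip permutation p = 0.0156). Ifnl2 (ENSMUSG00000059128) lies on chromosome 7 from 28508784 to 28510532 in GRCm38.p6, the assembly also called mm10. Ifnl3 (ENSMUSG00000060747) lies on the same chromosome from 28522833 to 28524401. The genes are close paralogs, so their separate counts depend on how reads were assigned to them and their sum was tested.

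Interferon lambda UMIs were seen in 1.71% of pDC-like cells (exact binomial 95% interval 1.10% to 2.53%). The count of 0 of 885 in all other assigned cells, with a median depth of 2285 UMIs, allows a share of up to 0.339% of cells with a UMI. The limit was 0.616% for 487 macrophage-like cells, 1.97% for 152 cDC2-like cells, 1.79% for 168 T/IEL-like cells and 8.82% for 34 migratory dendritic cell-like cells. The cDC2-like cells were deeper than the pDC-like cells, and their limit lies within the pDC-like interval. After thinning each cell to 1000 UMIs the share per mouse was 0.531% ± 0.575 (SD, n = 8) in pDC-like cells and 0 in the others, above 0 in 7 of 8 mice (exact sign-flip permutation p = 0.0156). It was 0.341% without Male4 (exact sign-flip permutation p = 0.0312), 0.294% on thinning to 500 UMIs, 0.985% on thinning to 2000 UMIs and 1.84% without thinning. Thinning left out 220 of the 487 macrophage-like cells as too shallow. As a measure of free RNA, Siglech, a pDC surface receptor, was seen in 99.9% of pDC-like cells, 4.93% of macrophage-like, 15.1% of cDC2-like and 7.74% of T/IEL-like cells. At 1000 UMIs these shares were 95.5%, 3.35%, 3.80% and 2.74%. Siglech was also seen in 73.1% of the 26 cycling cells and 90.9% of the 11 cells of mixed markers. Both groups are counted among the other assigned cells, which thus include some with pDC transcripts. All intervals and limits cover counting error alone.

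**Figure D1:**
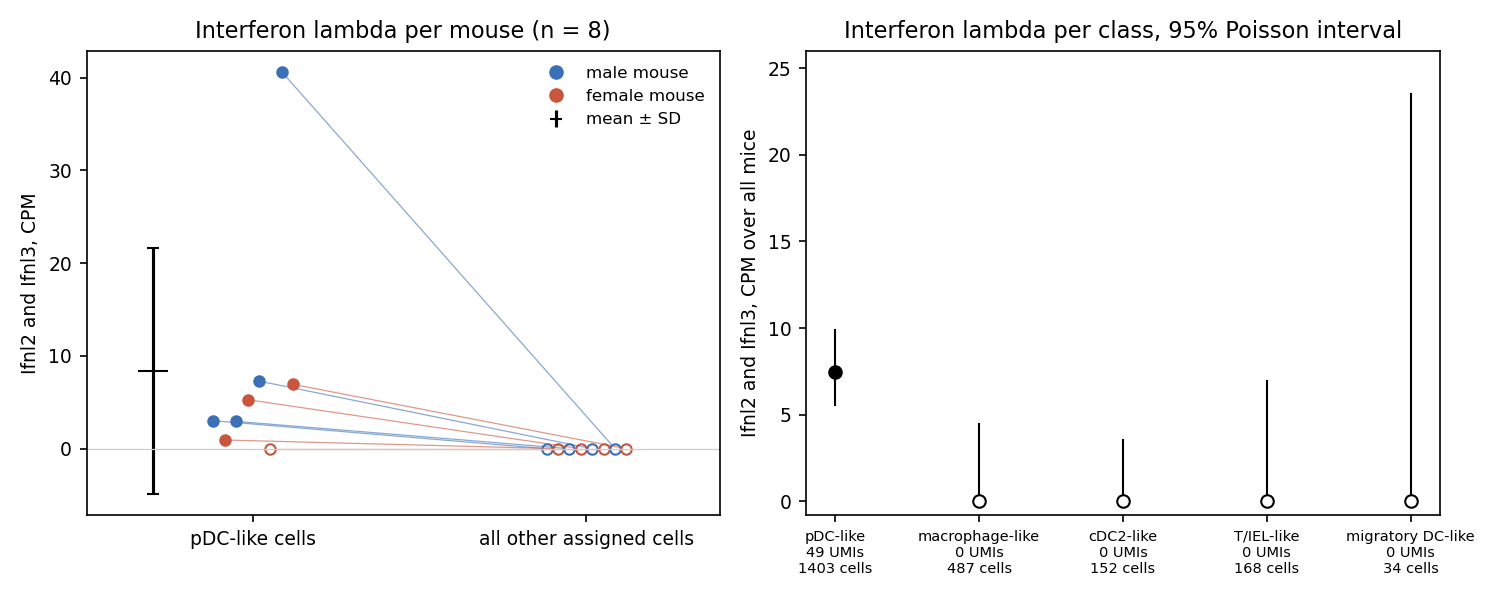
Interferon lambda (Ifnl2 and Ifnl3 summed) in counts per 1000000 UMIs (CPM). Left, each line joins the pDC-like and the other assigned cells of 1 mouse, open points mark 0 UMIs and the bar gives the mean ± SD (n = 8): 7 of 8 mice lie above 0, Male4 at 40.6 and the rest at 0 to 7.29. Right, each class over all mice with its 95% Poisson interval, 49 UMIs in pDC-like cells and 0 in each other class drawn.

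Type I interferons, which signal through a different receptor from interferon lambda, were close to absent in assigned cells. The pDC-like cells held 1 UMI of Ifnb1 and 1 UMI of Ifna2, and the other assigned cells held 0. The level was 0.376 ± 1.06 CPM (SD, n = 8) in pDC-like cells, above 0 in 1 of 8 mice, and did not pass the exact sign-flip permutation test (p = 1). The Ifnb1 UMI lay in the cell with 20 interferon lambda UMIs. The UMIs of Ifnb1 and Ifna2 both came from Male4, and without it the level was 0. With the alternative hashtag rule it was 2.27 ± 5.34 CPM (SD, n = 8; exact sign-flip permutation p = 0.5), from 16 UMIs in 3 pDC-like cells, 14 of them in 1 cell that carried more than 1 hashtag in the assignment used here. At the pDC-like level 0.868 UMIs would have been due in the other cells, so a difference was not detectable at this depth. Ifnb1 (ENSMUSG00000048806) lies on chromosome 4 from 88522025 to 88522794, and Ifna2 (ENSMUSG00000078354) on the same chromosome from 88683207 to 88683779. Ifng, the type II interferon, gave 4 UMIs in T/IEL-like and 2 in pDC-like cells. Ifnlr1, the specific chain of the interferon lambda receptor, was listed at 0 in the assigned cells, which allows up to 0.459 CPM in pDC-like cells and 1.06 CPM in the others.

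The fixed gene lists were then compared between pDC-like cells and the equally weighted mean of macrophage-like and cDC2-like cells, to describe the state of the cells that held interferon lambda. The genes of these lists were kept out of the clustering. Of 97 list genes tested, 35 were higher and 43 lower in pDC-like cells by edgeR at an adjusted p under 0.05 over all 3180 genes tested. Adjusted over the list alone, 36 were higher and 43 lower, and DESeq2 called 34 higher and 42 lower. In all, 2188 of the 3180 genes were called. The sums held 562642 to 901325 UMIs in pDC-like cells and 56205 to 283394 in the other classes. All log2 fold changes below are given with their SE, from 8 mice for pDC-like and macrophage-like and 6 mice for cDC2-like cells.

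MHC class II presentation was lower in pDC-like cells: of 11 genes tested, 10 fell and 1 (H2-Oa) rose, with a median log2 fold change of -1.82. H2-Oa stood at 184 CPM in pDC-like, 27.3 in macrophage-like and 309 in cDC2-like cells, so its rise was over macrophage-like cells. Not all falls were against both classes. In the same order H2-Ob stood at 18.5, 9.95 and 249 CPM and H2-DMb2 at 44.1, 56.7 and 339, so they fell mainly against cDC2-like cells. Ctss stood at 708, 2528 and 676 CPM, so its fall was against macrophage-like cells. H2-Eb1 and H2-Ab1, chains of the class II molecules, changed by -2.75 ± 0.07 and -2.37 ± 0.07. Cd74, the invariant chain, changed by -2.19 ± 0.06, and Ciita, the master activator of class II genes, by -2.36 ± 0.16. Each was lower in 8 of 8 mice, and the largest adjusted p of these 4 genes was 6.16e-15, for Ciita. As a set the list was lower by camera with a preset correlation of 0.01 (adjusted p = 8.49e-06), and this call was lost at adjusted p = 0.125 with an estimated correlation.

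Cytokine and chemokine transcripts were divided. Of 10 genes tested, 7 fell, 2 rose and 1 (Cxcl10) was not called by edgeR, with a median log2 fold change of -4.06. It was -4.94 with Cxcl10, Il1rn and Il1b taken from CPM over all mice and classes at 0 UMIs set to the floor. For Cxcl10 that floor in cDC2-like cells can overstate the fall, so -4.94 is no bound. Cxcl16, a membrane-bound chemokine, changed by -7.90 ± 0.27 (adjusted p = 6.72e-23) and Cxcl9, an interferon-induced chemokine, by -5.97 ± 0.83 (adjusted p = 1.28e-07), each in 8 of 8 mice. Cxcl9 stood at 1.74 CPM in pDC-like, 1076 in macrophage-like and 11.4 in cDC2-like cells, so most of its fall was against macrophage-like cells. Il1b, which encodes interleukin 1 beta, had 3 UMIs in pDC-like cells and changed by -9.14 ± 0.38 in edgeR. By CPM over all mice it was 889-fold lower (counting interval 304.2 to 4311, which leaves out the spread between mice). Il1rn, its receptor antagonist, had 0 UMIs in pDC-like cells and was at least 61.1-fold lower at the floor of 3 counts over the class. Cxcl10, an interferon-induced chemokine, had 6 UMIs in pDC-like (0.917 CPM), 193 in macrophage-like (233 CPM) and 0 in cDC2-like cells, where edgeR could not estimate its change; DESeq2 called it lower (adjusted p = 2.20e-05). The genes that rose were Ccl4, by 3.10 ± 0.18 (adjusted p = 1.01e-16), and Ccl3, by 1.69 ± 0.25 (adjusted p = 3.83e-07). Ccl3 stood at 199 ± 36.4 CPM in pDC-like, 193 ± 88.2 in macrophage-like and 20.9 ± 19.8 in cDC2-like cells, so its rise was over cDC2-like cells. Both were picked for naming after their values were seen, and both encode ligands of the receptor Ccr5. As a set the list did not pass camera (adjusted p = 0.0570; adjusted p = 0.304 with an estimated correlation). It passed as lower under 5 of 20 alternatives: without Male4 (adjusted p = 0.0476), with the alternative hashtag rule (adjusted p = 0.0134), without the mouse block (adjusted p = 0.0433), without the filter on low counts (adjusted p = 3.95e-06), and with sums of at least 20 cells, where cDC2-like cells no longer enter (adjusted p = 1.12e-04, range over the alternatives 3.95e-06 to 0.383).

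The endoplasmic reticulum and secretion list was higher in pDC-like cells: 14 of 25 genes rose, 2 fell and 9 were not called, with a median of 0.46. Xbp1, a transcription factor of secretory cells, rose by 1.69 ± 0.11 (adjusted p = 1.34e-15). Spcs2, part of the signal peptidase, rose by 1.26 ± 0.13 (adjusted p = 3.55e-10), and Hsp90b1, an endoplasmic reticulum chaperone, by 0.95 ± 0.09 (adjusted p = 2.87e-11), each in 8 of 8 mice. Dnajb9, a co-chaperone, rose by 1.08 ± 0.24 in 7 of 8 mice (adjusted p = 1.93e-04). The set was higher by camera (adjusted p = 0.0317), and this was lost at adjusted p = 0.403 with an estimated correlation, the highest of its alternatives (lowest 8.01e-05). It was also lost without the mouse block (adjusted p = 0.0597) and with sums of at least 20 cells (adjusted p = 0.235).

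Interferon receptor genes went both ways, with 3 higher and 2 lower of 5 tested and a median of 0.82. Ifnar2 and Ifnar1, the chains of the type I receptor, rose by 2.23 ± 0.12 (adjusted p = 1.86e-17; 8 of 8 mice) and 1.49 ± 0.18 (adjusted p = 8.19e-09; 7 of 8 mice). Il10rb, the chain that the interferon lambda receptor shares with interleukin 10, rose by 0.82 ± 0.16 (adjusted p = 2.82e-05; 7 of 8 mice), at 151 ± 18.4 CPM in pDC-like, 151 ± 43.3 in macrophage-like and 49.4 ± 25.8 in cDC2-like cells, so its rise was over cDC2-like cells. Ifngr1, of the interferon gamma receptor, changed by -2.98 ± 0.14 (adjusted p = 1.92e-19; 8 of 8 mice). The list as a set did not pass camera (adjusted p = 0.677).

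Of 12 nucleic acid sensing genes tested, 6 were higher, 4 lower and 2 not called, with a median of 0.16. Tlr7, the endosomal sensor of single-stranded RNA, rose by 3.08 ± 0.19 (adjusted p = 9.43e-16; 8 of 8 mice), at 223 ± 25.0 CPM in pDC-like, 104 ± 34.7 in macrophage-like and 5.46 ± 4.27 in cDC2-like cells. Irf7, a transcription factor of interferon genes, rose by 2.02 ± 0.22 (adjusted p = 7.81e-10; 8 of 8 mice), but stood at 165 ± 33.9 CPM in pDC-like and 166 ± 37.3 in macrophage-like against 9.33 ± 12.4 in cDC2-like cells. Slc15a4, a lysosomal transporter needed for endosomal sensing, rose by 1.05 ± 0.16 (adjusted p = 5.92e-07; 8 of 8 mice). Ifih1, a cytosolic sensor of double-stranded RNA, changed by -2.74 ± 0.31 (adjusted p = 1.80e-09; 8 of 8 mice). The list as a set did not pass camera (adjusted p = 0.655).

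The dissociation and immediate early response list, kept as a sign of handling, was lower in pDC-like cells: 13 of 15 genes fell and 2 rose, with a median of -1.50. Atf3, a stress-induced transcription factor, changed by -6.20 ± 0.28, and Dusp1, a phosphatase of stress kinases, by -2.86 ± 0.16. Ier2 and Nr4a1, both immediate early genes, changed by -2.78 ± 0.16 and -2.44 ± 0.13. Each was lower in 8 of 8 mice, with adjusted p of 1.89e-16 for Ier2, the largest of the 4. The set was lower by camera (adjusted p = 2.77e-04), and this was lost at adjusted p = 0.304 with an estimated correlation. These differences run alongside those of the other lists in the same cells and of median depth, 4607 UMIs in pDC-like against 1075 in macrophage-like and 6865 in cDC2-like cells.

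**Figure D2:**
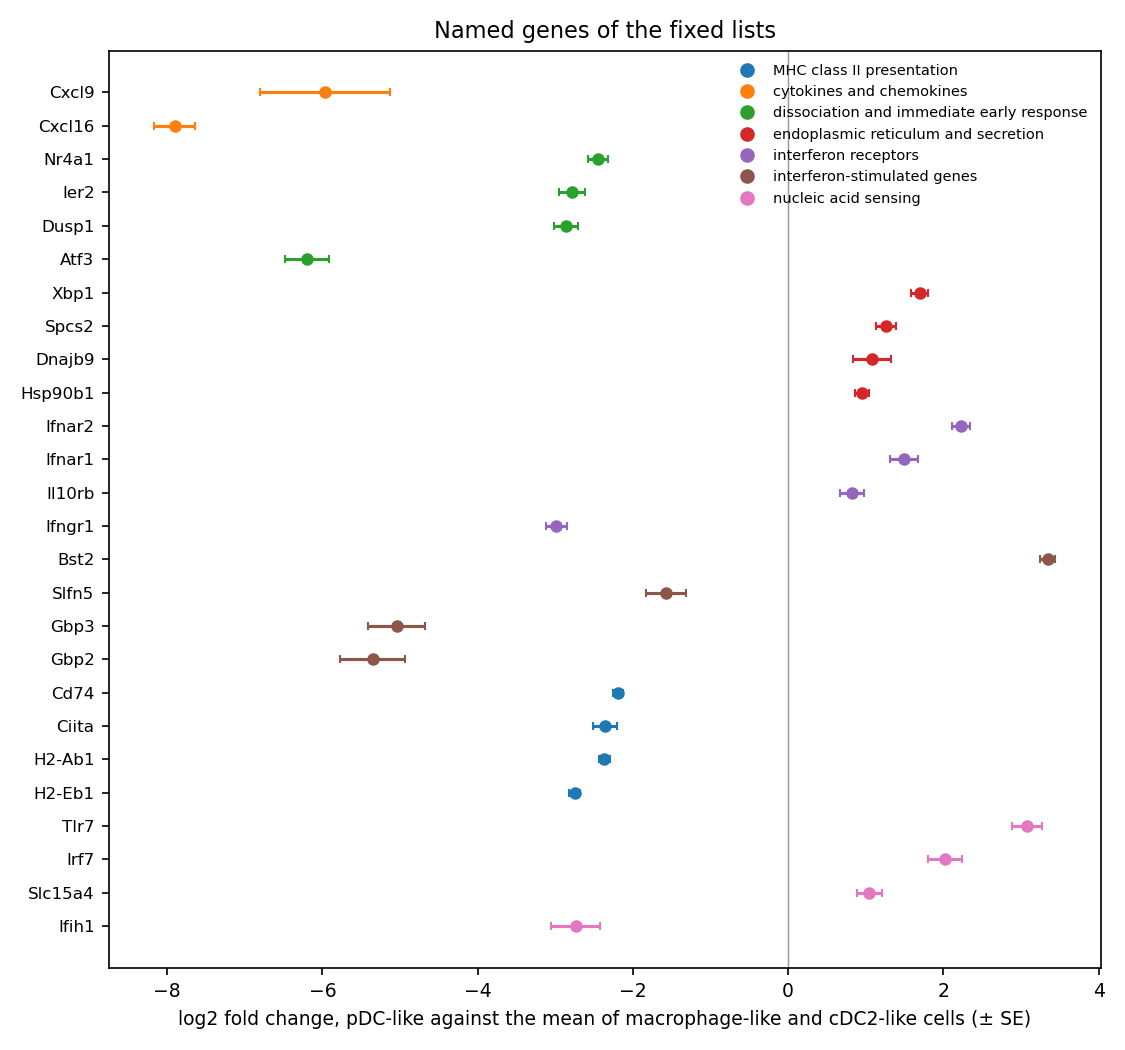
Log2 fold change (± SE) of the named genes of the fixed lists, pDC-like cells against the mean of macrophage-like and cDC2-like cells, coloured by list. Values run from -7.90 for Cxcl16 to 3.35 for Bst2; Il1b and Il1rn, with at most 3 UMIs in pDC-like cells, are not drawn.

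Interferon-stimulated genes, which respond to interferons, were compared between the 3 myeloid classes as a measure of tonic interferon response. The list does not tell type I, lambda and gamma interferon apart. Ifngr1, of the interferon gamma receptor, stood at 30.5 CPM in pDC-like, 234 in macrophage-like and 257 in cDC2-like cells. Of the 43 genes of the list, 19 were tested. In macrophage-like cells 13 of these 19 genes rose against the other classes, 2 fell and 4 were not called, with a median of 0.91. Gbp3 and Gbp2, interferon-induced GTPases, rose by 4.13 ± 0.28 and 2.94 ± 0.37 there, Zbp1, a sensor of Z-form nucleic acid, by 3.43 ± 0.30, and Slfn5, a Schlafen family member, by 2.22 ± 0.26 (SE; largest adjusted p of the 4 2.61e-08). In cDC2-like cells 12 fell, 2 rose and 5 were not called, with a median of -1.21. There Zbp1 changed by -2.63 ± 0.47, Epsti1 by -2.58 ± 0.27 and Bst2 by -2.38 ± 0.15, while Gbp2 rose by 2.41 ± 0.41 (SE; largest adjusted p of the 4 1.83e-05).

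In pDC-like cells 7 of the 19 rose, 5 fell and 7 were not called, and adjusted over the list alone 8 rose. Of the list genes too low to test, only Ifi44 had a higher CPM in pDC-like than in macrophage-like cells. Bst2, a tethering protein that inhibits virus release and is also a pDC surface marker, rose by 3.35 ± 0.10 (adjusted p = 1.78e-24; 8 of 8 mice), at 2454 ± 72.5 CPM. Gbp2 and Gbp3 changed by -5.35 ± 0.42 (adjusted p = 2.42e-13) and -5.04 ± 0.37 (adjusted p = 5.13e-14), each in 8 of 8 mice, and Slfn5 by -1.57 ± 0.26 (adjusted p = 2.42e-06; 7 of 8 mice). Slfn5 stood at 38.5 CPM in pDC-like, 226 in macrophage-like and 56.8 in cDC2-like cells, so most of its fall was against macrophage-like cells. Over the 19 genes the median was 0.21 and the mean -0.29, of opposite sign. By camera the list was higher in macrophage-like cells (adjusted p = 0.0347) and lower in cDC2-like cells (adjusted p = 1.38e-04), and did not pass in pDC-like cells (adjusted p = 0.655). The macrophage-like and cDC2-like calls were lost with an estimated correlation, at adjusted p = 0.607 and adjusted p = 0.153. In pDC-like cells the direction turned and the list passed as lower without the filter on low counts (adjusted p = 0.0254) and with sums of at least 20 cells (adjusted p = 0.0414), and it turned without passing when Male1 was left out (adjusted p = 0.989). Without the macrophage-like cluster of low UMI counts, where pDC-like cells are compared with cDC2-like cells alone, the list passed as higher (adjusted p = 0.00373, range over the alternatives 0.00373 to 0.989).

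**Figure D3:**
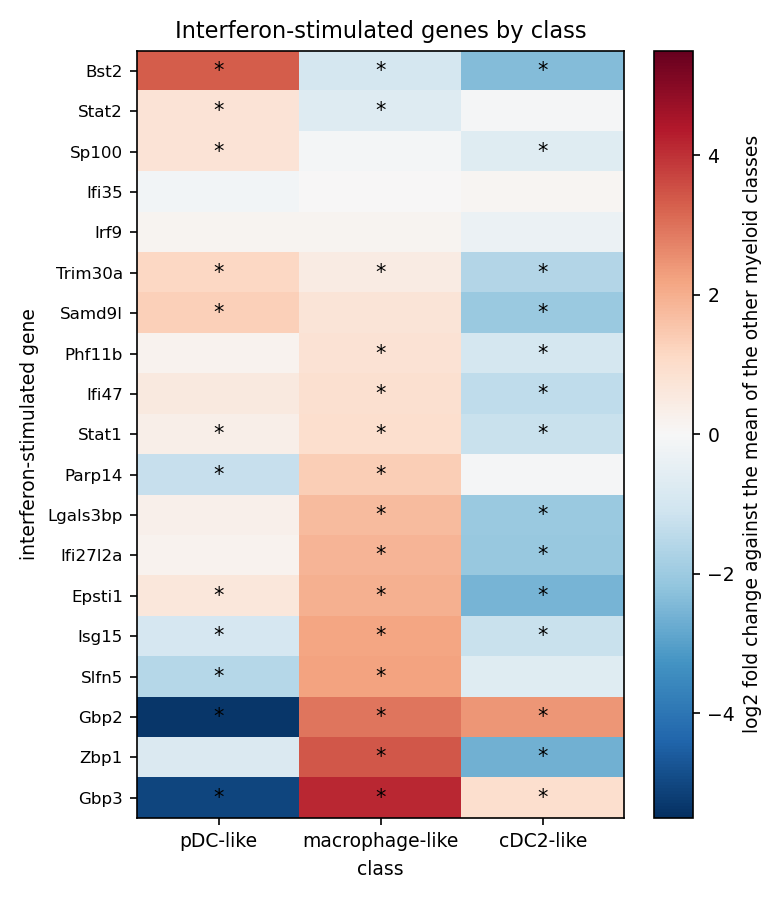
Log2 fold change of 19 interferon-stimulated genes (y axis) in each myeloid class against the mean of the other classes, as colour from blue (lower) to red (higher). A star marks adjusted p under 0.05 in edgeR: 12 of 19 genes in pDC-like, 15 in macrophage-like and 14 in cDC2-like cells.

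Surface antibody tags separated pDC-like from the macrophage-like and cDC2-like cells of the same mouse. No file pairs the tag numbers with antibodies, so names follow the order of the antibody list in the labels. They are used only for 7 tags that, of all tags, correlated best across cells with the transcript of their listed antibody. That check covered 11 genes and was chosen after the data were seen. The correlation was 0.728 for CD8a and 0.730 for Ly-6C, but only 0.196 for CD45R/B220 and 0.206 for CD11c. As Ptprc is the gene of all CD45 forms, it cannot show that a tag reads the B220 form. That name thus rests on the order of the list. Tag levels are means over cells of a share of each cell's tag counts, with a median of 239 counts per assigned cell. A cell without a count enters at the lowest value. The differences thus also reflect how many cells had a count, and are no fold in surface protein. The tag listed as CD45R/B220, a pDC and B cell form of CD45, was higher by a log2 difference of 6.81 ± 0.32 (SD, n = 8). CD8a was higher by 5.80 ± 0.73 and Ly-6C by 4.35 ± 0.56 (SD, n = 8). Their transcripts Cd8a and Ly6c2 stood at 416 against 8.54 CPM and 735 against 61.9 CPM, pDC-like against other, while Ptprc, the gene of all CD45 forms, stood at 1135 against 1086 CPM. Cd8a and Ly6c2 were open to the clustering, so these transcript values are no independent result.

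CD11b, an integrin chain used in the sort, was lower in pDC-like cells by a log2 difference of -6.34 ± 0.27, and I-A/I-E, the class II molecules, by -2.16 ± 0.25 (SD, n = 8). The transcript H2-Ab1 stood at 1510 against 7363 CPM and Itgam, of CD11b, at 0.459 against 158 CPM. H2-Ab1 was kept out of the clustering. Itgam, also on the cDC2 marker list, was open to it, as were Itgax and Itgae below, so their values are no independent result. CD11c, the other sort antibody, differed by 0.36 ± 0.54, and CD103 by 0.41 ± 0.79 (SD, n = 8), and neither passed; their transcripts Itgax and Itgae were lower in pDC-like cells, at 392 against 515 and 80.1 against 245 CPM. Among tags given by number, ADT18, ADT16 and ADT7 were higher, by 3.75, 1.47 and 1.09. ADT4, ADT13, ADT17 and ADT19 were lower, at -4.28, -3.03, -2.87 and -2.30. In all, 6 tags were higher, 9 lower and 6 not called. Of the 15 called, 14 moved one way in 8 of 8 mice with an exact sign-flip permutation p of 0.00781, the smallest that 8 mice can give (adjusted p = 0.0117 over 21 tags), and ADT21 did so in 7 of 8.

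**Figure D4:**
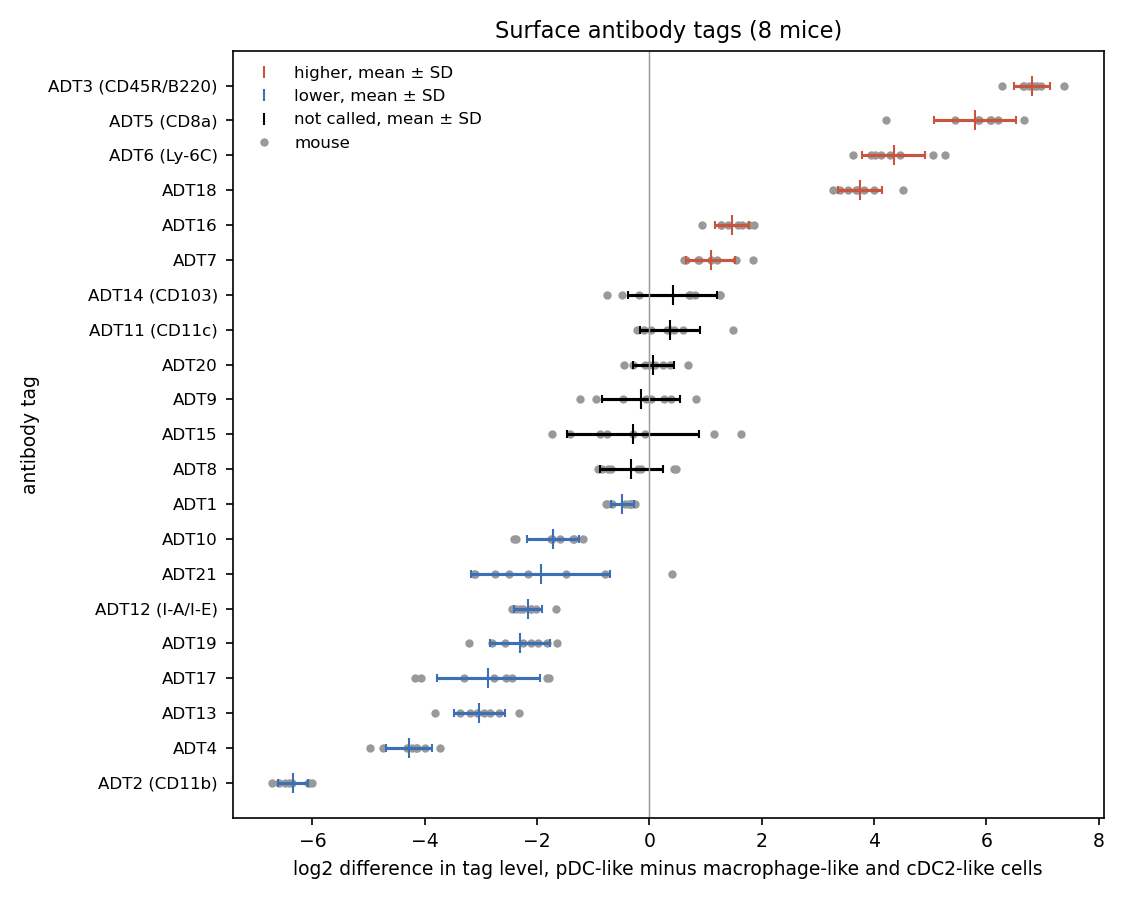
Difference in surface antibody tag level (log2, tag counts per 10000 plus 1) between pDC-like cells and the macrophage-like and cDC2-like cells of the same mouse. Points are 8 mice and bars the mean ± SD; red tags were higher (6), blue lower (9) and black not called (6), with CD45R/B220 at 6.81 and CD11b at -6.34 at the ends.

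Male and female mice were compared within each class, as the labels give the sex of each mouse. In pDC-like cells, with 4 against 4 mice and 7377 genes tested, edgeR called 25 genes, of which 10 were on a sex chromosome or among the label checks. Of the other 15, 7 were higher in male and 8 in female mice. They include Gm47283 and Gm42418, for which no chromosome was given, so a place on a sex chromosome was not excluded for them. The chemokine receptor genes Cxcr4 and Ccr9, which guide cells to bone marrow and to the small intestine, went opposite ways. Cxcr4 was higher in males by a log2 fold change of 0.56 ± 0.10 (SE; adjusted p = 0.00395), at 367 ± 55.5 against 250 ± 31.5 CPM. Ccr9, also a marker used to name the class, was higher in females, at -0.25 ± 0.05 (SE; adjusted p = 0.0188) and 1874 ± 112 against 2229 ± 133 CPM. Also higher in males were Zfp36l2, an RNA-binding protein (0.46), Dynll1, a dynein light chain (0.37), Ahnak, a large scaffold protein (0.34), and Pop4, a subunit of ribonuclease P (1.10). Also higher in females were the predicted gene Gm47283 (-0.73), Tasor2 (-0.58), AY036118 (-0.50), H2-Q6, a class I MHC gene (-0.48), and Gm42418 (-0.40). Gm47283 was lower in males by a similar size in cDC2-like (-0.86 ± 0.22) and T/IEL-like cells (-0.90 ± 0.37; SE), though not called there. Gm42418, at 7592 ± 730 against 10022 ± 1462 CPM (SD, n = 4 each), overlaps ribosomal RNA sequence. In each gene named so far the male and female mice did not overlap; over all genes tested 3.92% did not overlap, where chance gives 2.86% for 4 against 4. The 4 remaining genes, Ly6d, Hspa8, Pim1 and Peli1, overlapped and are named after their values were seen. The count of 15 was 5 by DESeq2, 40 without the filter on low counts, 9 without Female2, 9 under a stricter cell filter and 9 without the clusters in which most cells carried more than 1 hashtag.

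In macrophage-like cells, with 4 against 4 mice, edgeR called 0 genes beyond Xist, while 77 of 1618 had an unadjusted p under 0.05 and DESeq2 called 1. The count was 7 without Female1, 1 without Female3 and 14 without the filter on low counts. In cDC2-like cells, with 3 against 3 mice, 2 genes were called. Id2, a regulator of dendritic cell fate, was higher in males by 0.98 ± 0.16 (SE; adjusted p = 0.00649), at 1212 ± 185 against 628 ± 86.5 CPM. Mmp12, a macrophage elastase, was higher in females, at -2.16 ± 0.35 (SE; adjusted p = 0.00719) and 44.6 ± 3.53 against 207 ± 79.3 CPM. In T/IEL-like cells, with 3 against 3 mice, 1 gene was called: Gzmb, a cytotoxic granule protease, was higher in females, at -0.70 ± 0.14 (SE; adjusted p = 0.0399) and 6160 ± 1221 against 10090 ± 572 CPM. The cDC2-like count was 4 without Male1, 1 without Male2 or without Female3, and 0 without Female1 or without Male4, and 11 without the filter. The T/IEL-like count was 6 without Male1, 2 without Female1 or without Female3, 0 without Male2, Female2 or Male4, 0 with the alternative hashtag rule, and 2 by DESeq2 or without the filter. A test of whether the sex difference in pDC-like cells departed from that in the other myeloid classes, chosen after the results were seen, called 0 of 3180 genes by edgeR, while 131 of the 3099 genes off the sex chromosomes and label checks had an unadjusted p under 0.05. It covered 14 of the 15 genes called in pDC-like cells. Single pairs of classes were compared for Gm42418 and AY036118 alone.

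Between the sexes, 4 lists passed camera. In macrophage-like cells the interferon-stimulated genes were lower in males, with a median log2 fold change of -0.60 over 15 genes (adjusted p = 3.00e-06), a call lost at adjusted p = 0.118 with an estimated correlation. The cytokine and chemokine list was also lower in male macrophage-like cells, with a median of -0.43 over 9 genes (adjusted p = 4.24e-05; adjusted p = 0.0270 with an estimated correlation). Taken per mouse, a test chosen after the results were seen, the mean log2 level of these genes was 8.48 ± 0.29 in male and 9.14 ± 0.34 in female mice (SD, n = 4 each) and did not pass (exact permutation p = 0.0571, adjusted p = 0.214 over 5 tests). In pDC-like cells the interferon-stimulated genes had a median of -0.13 over 26 genes (adjusted p = 0.0488) and the immediate early genes a median of 0.25 over 14 genes (adjusted p = 0.0487), each lost at adjusted p = 0.874 with an estimated correlation. In none of these lists was a single gene called over all genes tested. Adjusted over the list alone, 1 of 77 list genes passed in macrophage-like cells, and 0 of 101 in pDC-like, 0 of 66 in cDC2-like and 0 of 21 in T/IEL-like cells.

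The share of cells in each class did not differ detectably between male and female mice (exact permutation test, 70 arrangements, smallest possible p 0.0286; adjusted p 0.947 to 0.971 over 8 classes). At that smallest p a single class could not pass after adjustment. The pDC-like cells made up 60.7% ± 9.49 of male and 62.8% ± 12.5 of female cells (SD, n = 4 each). Macrophage-like cells made up 20.1% ± 1.33 and 21.9% ± 4.73, cDC2-like cells 7.71% ± 6.59 and 5.66% ± 3.43, and T/IEL-like cells 8.31% ± 7.33 and 6.13% ± 5.65. The sort and the hashtag staining also set these shares.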

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

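The tests of explanations, the readings of the counts over other groupings of the mice and the test of a difference between the sexes in the class contrast were chosen only after the results were seen. Extreme mice were searched for in 89 groups of 4 to 8 mice with Dixon's gap over range, which chance alone passes in about 1 in 20 groups. That is 4.45 groups by chance, and 9 passed.

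Interferon lambda in pDC-like cells was 40.6 CPM in Male4 and 0 to 7.29 CPM in the other mice, and after thinning the share of positive cells was 1.86% in Male4 and at most 0.586% in the others. Free RNA as the source would have put 21.3 interferon lambda UMIs in the other assigned cells, and if lesser depth alone hid it there, 10.4 positive cells would still have been due at their depth; 0 were seen of either, which argues against both as the whole account. Without Male4 these counts fell to 8.75 UMIs and 6.36 cells. With the alternative hashtag rule 1 UMI in 1 other cell was seen, where 22.7 UMIs and 11.4 cells were due. The gap of Male4 over the range was 0.821 and fell to 0.315, below the critical value for 8 mice, without its single cell of 20 UMIs, in line with 1 cell setting that mouse apart. The same holds for the thinned share, whose gap over the range fell from 0.685 to 0.502 without that cell. Male4 still stood highest without that cell, at 10.6 CPM and a thinned share of 1.18%. It gave 8 of the 24 positive pDC-like cells, so its share does not rest on 1 cell alone. No biological explanation was tested for Male4.

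Gm42418 and AY036118 were higher in female pDC-like cells, and AY036118 stood at 2452 CPM in Female8 against 1702 to 1795 in the other females. A difference between the mice that acts on all their cells alike, such as in handling or lysis, would also appear in the cDC2-like cells of the same 6 mice. There the log2 difference, male against female, was 0.01 ± 0.09 for Gm42418 and 0.02 ± 0.12 for AY036118 (SE), against -0.29 ± 0.05 and -0.36 ± 0.08 in pDC-like cells. In T/IEL-like cells it was 0.44 ± 0.20 and 0.32 ± 0.26, also apart from pDC-like cells. In macrophage-like cells of all 8 mice, however, it was -0.46 ± 0.25 and -0.45 ± 0.33, about as in pDC-like cells of these mice (-0.40 ± 0.06 and -0.50 ± 0.08). The gap between cDC2-like and pDC-like cells, 0.34 on average over both genes, was more than 2 SE for each, but for AY036118 it fell to 0.24 ± 0.14 without Male1 and to 0.24 ± 0.14 without Female3. Against the macrophage-like and cDC2-like cells together, the sex difference in pDC-like cells was not detectably different (log2 difference -0.12 and -0.22, edgeR adjusted p = 1 for each). The difference between male and female mice was called in pDC-like cells, but whether it comes from sex or from another difference between these mice cannot be told apart here, and sex as its cause was not tested apart from the mice.

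Other extreme mice are given as values. In the contrast of pDC-like with the other myeloid classes, Spcs2 was at a log2 difference of 2.74 in Female8 (others 0.77 to 1.60). Slfn5 was at 1.93 in Male1 (others -3.05 to -0.91). Gbp3 was at -0.98 in Male1 (others -6.33 to -3.95). Within pDC-like cells, Cxcr4 was at 203 CPM in Female1 (other females 265 to 268). Peli1 was at 113 CPM in Male1 (other males 84.8 to 86.9). Eif2s3y, on the Y chromosome, was at 0.9497 CPM in Female1, which is 1 UMI, and 0 in the other females. With the others at 0 the gap over range is 1 for any count, so this is no sign of an extreme mouse.

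The contrast of Ccl4 between pDC-like and the other myeloid classes was larger in male than in female mice by a log2 difference of 1.38 in a test of the difference itself (edgeR adjusted p = 0.794 over all genes, and 0.0484 adjusted over the list alone, with 97 genes). Cells with more than 1 hashtag, not used in the comparisons, held 16 interferon lambda UMIs in 15 of 678 cells, each with UMIs of at least 12 pDC markers; 4 of the 15 were in clusters outside the pDC-like class. They also held 15 Ifnb1 UMIs in 2 cells, 14 of them in a cell of the cluster led by interferon-stimulated genes, which had 0 interferon lambda UMIs.

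Other groupings of the same mice were fitted to see whether chance gives as many called genes. For the list genes between classes the real labels gave 78 calls. The highest of 99 others gave 47, and 1 of 100 gave as many. The classes were clusters of the same cells, and 2188 of 3180 genes were called between them. Fewer calls from other labels were thus due beforehand, so these counts say nothing about chance. For pDC-like cells in male and female mice the real split gave 15 genes and the highest other 5. As many were given by 1 of 35 splits, the smallest share that 35 splits can give. The real split thus stood above all others, but so few splits cannot exclude chance. They also cannot tell sex from another difference between these mice. For macrophage-like cells the real split gave 0 genes and the highest other 1; each split gives at least 0, so the count of 35 of 35 says nothing about chance. For cDC2-like and T/IEL-like cells the 10 splits are too few: the real counts were 2 and 1, the highest others 4 and 1, reached by 2 and 3 splits.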

How the results depend on the processing

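The alternatives that leave out a single cell or cluster were chosen only after the results were seen; the others were planned. Of all recomputed values, 338 kept their direction and side of the threshold, or stayed within 1.5 times a count, 6 turned direction, 7 no longer passed, 6 newly passed and 28 moved. Interferon lambda kept direction and call under all 17 alternatives (3.77 to 9.57 CPM), as did its share of cells under all 19 (0.294% to 1.84%). Where the other cells held 0 UMIs the direction could not turn, and p followed from the number of mice with a UMI alone. The kept calls are therefore little sign of stability. The count of 0 in the other cells became 1 UMI with the hashtag rule (0.304 CPM). Class shares stayed at 0 called, but with a smallest possible p of 0.0286 a single class cannot pass after adjustment over 8 classes. Tags stayed at 6 to 7 higher and 8 to 9 lower. Leaving out each mouse gave 3.77 to 9.57 CPM for interferon lambda, 0.341% to 0.607% for its share, 6 tags higher and 9 lower, and 32 to 36 list genes higher and 41 to 46 lower. Type I interferon ranged from 0 without Male4 to 0.430 CPM, and was 2.27 CPM with the hashtag rule, passing in none. Where a value below moved, the cause was not tested, except that fewer or more genes or classes entered where said. An estimated correlation above the preset 0.01 also widens the null of camera. The estimate was 0.157 to 0.364 for the lists in pDC-like cells that lost their call, but -0.137 for receptors and 0.0015 for sensing.

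List genes lower in pDC-like cells numbered 70 with no filter on low counts, where more genes are tested. Camera adjusted p for cytokines and chemokines was 0.0134 with the hashtag rule, 0.0433 without the mouse block, 3.95e-06 without the filter and 1.12e-04 with sums of at least 20 cells, where cDC2-like cells do not enter. With an estimated correlation the lists had 0.304 (dissociation), 0.403 (endoplasmic reticulum), 0.125 (MHC class II), 0.607 (interferon-stimulated, macrophage-like) and 0.153 (cDC2-like). The endoplasmic reticulum list had 0.0597 without the block and 0.235 with 20 cells. Receptors turned direction with 20 cells (0.896), and sensing turned without the filter (0.269) and with 20 cells (0.679). Interferon-stimulated genes in pDC-like cells passed without the macrophage-like cluster of low UMI counts (0.00373), and turned without the filter (0.0254), with 20 cells (0.0414) and without Male1 (0.989). Ranges on leaving out each mouse were 0.0476 to 0.106 for cytokines, 4.28e-05 to 5.98e-04 for dissociation, 0.0170 to 0.0465 for endoplasmic reticulum, 0.626 to 0.842 for receptors, 9.40e-06 to 2.10e-05 for MHC class II and 0.590 to 0.778 for sensing. For interferon-stimulated genes they were 0.590 to 0.989 in pDC-like, 9.64e-04 to 0.0311 in macrophage-like and 3.23e-05 to 5.89e-04 in cDC2-like cells.

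Genes between the sexes in pDC-like cells numbered 9 with the stricter cell filter, 9 without the clusters of mostly more than 1 hashtag, 40 without the low-count filter, 5 by DESeq2, and 9 to 13 on leaving out each mouse. Macrophage-like cells gave 14 without the filter, 1 by DESeq2 and 0 to 7. The cDC2-like cells gave 11 without the filter and 0 to 4. The T/IEL-like cells gave 0 with the hashtag rule, 2 without the filter, 2 by DESeq2 and 0 to 6. No pairing of the mice by their numbers was seen, though so few pairs cannot exclude it. Residual correlations of mice with the same number were -0.03, -0.01 and 0.03 in pDC-like and 0.13, -0.01 and 0.00 in macrophage-like cells. A block on the number, without Male4 and Female8, gave 7 genes in cDC2-like and 0 in T/IEL-like cells. Scrublet called 4 cells, 0 of them assigned, so that alternative tests nothing. Sums of at least 20 cells left too few mice to test sexes in cDC2-like and T/IEL-like cells, and without the low-UMI cluster the macrophage-like class no longer entered. Depth limits macrophage-like cells most: 220 of 487 had too few UMIs for thinning.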

Other observations

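The tests of hypotheses in this part were chosen only after the results were seen. Several list genes were too low for the gene comparison and are given as counts over all mice, with no test. Il12a, a subunit of interleukin 12, gave 46 UMIs in 35 pDC-like cells and 0 in other assigned cells, at least 6.66-fold higher than their floor, with 19.97 UMIs due there. Ifi44, an interferon-stimulated gene, gave 249 UMIs in pDC-like cells (38.1 CPM), 7 in macrophage-like (8.46 CPM) and 0 in cDC2-like cells. Tlr9, the endosomal sensor of DNA, gave 45 UMIs in pDC-like cells (6.88 CPM, 95% Poisson interval 5.02 to 9.21), 4 in macrophage-like (4.84 CPM, 1.32 to 12.4) and 0 in cDC2-like cells, so the first 2 intervals overlap. Tlr13, a sensor of bacterial ribosomal RNA, gave 1 UMI in pDC-like (0.153 CPM), 63 in macrophage-like (76.2 CPM) and 40 in cDC2-like cells (38.2 CPM). Outside the compared classes, Ccl22 stood at 3176 CPM in migratory dendritic cell-like and 0.917 CPM in pDC-like cells, and Ccl5 at 25575 CPM in T/IEL-like and 17.0 CPM in pDC-like cells.

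Among macrophage-like cells, a hypothesis is that tonic interferon response differs between male and female mice, as the list test was lower in males, though that call was lost with an estimated correlation (adjusted p = 0.118). The mean log2 level of the 15 interferon-stimulated genes was 7.64 ± 0.22 in male and 8.13 ± 0.34 in female mice (SD, n = 4 each; exact permutation p = 0.0857, adjusted p = 0.214 over 5 tests). Without the cluster of low UMI counts the difference was -0.57 over the 4 genes left (exact permutation p = 0.343), so whether that cluster carries it cannot be told apart from a difference of sex with so few cells. The values leave both open.

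Of the 46 assigned cells in the pDC-like cluster led by interferon-stimulated genes, 4 held interferon lambda (8.70%, 95% exact interval 2.42% to 20.8%), against 18 of 1173 other pDC-like cells of the same 7 mice (1.53%, 0.912% to 2.41%). The cluster held 23 interferon lambda UMIs, 20 of them in the 1 Male4 cell that held most. Male4 gave 2 of the 4 positive cells, and without it the shares were 2 of 42 (4.76%, 0.582% to 16.2%) and 12 of 1037 (1.16%). The hypothesis that interferon lambda may be more frequent in pDC-like cells with an interferon response was tested within mice. The share was higher in 3 mice and lower in 3 (exact sign-flip permutation p = 0.25, and p = 0.5 without Male4), so the cells are too few to tell. The level in male mice was 13.5 ± 18.2 CPM and in female mice 3.29 ± 3.35 CPM (SD, n = 4 each), and a difference of sex could not be told from the spread between mice (exact permutation p = 0.314). Without Male4 the male mean was 4.42 ± 2.49 CPM (SD, n = 3; exact permutation p = 0.629).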
